A study of Mus musculus with 18 samples.

How the data were processed

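Poly-A RNA from C2C12 myotubes was sequenced on an MGI instrument as 18 strand-directional libraries with 100 bp paired ends, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the mouse build GRCm38 (mm10). The annotation release, the filters and the strand setting used for counting are not given in the sources used here, so antisense and overlapping genes cannot be told apart with certainty. The authors deposited 1 table of expected counts, the estimated fragments per gene that RSEM gives, for 48795 Ensembl gene IDs; 9.27% of values were not whole. RSEM divides reads between near-identical copies by estimation, so values of genes with close paralogs (Serpina3n, Ctla2a, Amy1, Mt1, histones and myosin heavy chains among those tested) are less certain than their counts imply. Symbols and coordinates came from GENCODE mouse release 21 (GRCm38, Ensembl 96), which named 48349 IDs; the other 446 held 0.038% of counts and were kept in library sizes and tests.

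Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which kept 15436 of 27028 genes with any count, and scaled by TMM. A model with 1 mean per group was fitted to all 18 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust), and each comparison was tested with glmQLFTest and Benjamini-Hochberg adjustment at 0.05. Standard errors are the fold change divided by the square root of F, and 95% intervals use the same error. CPM are TMM scaled, with SD over n = 3 libraries; the detection floor is 3 counts, and such limits cover counting error only. There were 11 comparisons: dexamethasone against control, each ginsenoside dose against control and, with dexamethasone, against dexamethasone alone, dexamethasone against none at each dose, the interaction at each dose and the doses against each other. The 30 gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 30 lists of a comparison, with fry and with camera's estimated correlation beside it. With the estimated correlation 8 of the 17 list calls of dexamethasone against control held: glucocorticoid targets (0.0016), adipocyte (0.0079), mitochondrial biogenesis (0.011), osteoblast (0.018), atrophy (0.046), myoblast (0.046), inflammatory (0.048) and stress response genes (0.048). List members were written down from general knowledge, and a gene could stand in more than 1 list.

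Groups, comparisons, tests, lists, the rule for genes to name and most alternatives were fixed before the data were examined. The rule took, per comparison, genes that passed with an average log2 CPM of at least 1 and no overlap between groups: the 8 largest rises and 8 largest falls, the 2 members with the smallest adjusted p of each list, and always Fkbp5, Tsc22d3, Klf15, Fbxo32, Trim63, Foxo1, Mstn, Ppargc1a, Myh4 and Myog. Where fewer than 10 genes passed it took all of them and the 4 with the smallest p. Genes named outside their own comparison under this rule (Edn1 with dexamethasone, Lgr6 at 20 µM alone, Vgll2 and the genes in the closing section's Wnt test) were chosen after their values were seen, as was the correlation of dexamethasone responses with and without ginsenoside. The dexamethasone score is the mean log2 CPM of raised minus lowered genes with an absolute log2 change above 1, taken for each dose from the dexamethasone comparison at the other dose, which shares no library with it. Scores of groups were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1.

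Alternatives tried were median-ratio size factors, no composition scaling, no low-count filter, DESeq2 1.42.0, only the compared groups in the model, a replicate block, leaving out each library, a test against a 1.2-fold change, and variations of the list, score and correlation tests. Added after seeing the data were leaving out replicate 2 of the 20 µM group or replicate 2 of the dexamethasone group, limma voom with quality weights, offsets for transcript length and GC content, the sterol level of each library as a covariate, and the difference in mean log2 CPM of each list without each library of the groups compared. Effects against shared libraries were compared with unchanged groups simulated against the same libraries, each gene drawn independently. The main test was run on simulated counts drawn from the means and dispersions of the real libraries, for well-expressed genes. Changes of 1.25, 1.5, 2 and 4-fold were each given to 150 genes over 3 runs. That is more changed genes per run than the ginsenoside comparisons called, which eases the adjusted threshold, so recovery in those comparisons may be lower. For 20 µM with dexamethasone against dexamethasone alone (15323 genes) it recovered 42.7% of genes changed 1.25-fold, 88.7% of those changed 1.5-fold and 98% of those changed 2-fold. For 20 µM against control (15336 genes) the shares were 49.3%, 82.7% and 98%. False calls over 3 runs numbered 28 and 30. Scores and figures used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.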

Results

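RNA was sequenced from C2C12 myotubes, fused muscle fibres grown from a mouse myoblast line and differentiated for 5 days in horse serum. The 18 libraries fell into 6 groups of 3. Control cultures received 0.1% DMSO for 36 h, and 2 groups received ginsenoside Rc, a triterpenoid saponin from ginseng, at 10 µM or 20 µM for 36 h. The other 3 groups were exposed to 200 µM dexamethasone, a synthetic glucocorticoid, for the last 24 h, after 12 h with vehicle, with 10 µM ginsenoside Rc or with 20 µM ginsenoside Rc. The design asks what the glucocorticoid does to myotubes and whether pre-treatment with ginsenoside Rc changes that response. Whether the ginsenoside stayed on during dexamethasone is not known here, and DMSO is recorded only for the groups without ginsenoside. Library totals ranged from 32.4M to 45.4M expected counts (M for 1e6), and 15436 genes were tested. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

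The first principal component of log2 CPM (counts per 1e6) held 70.9% of the variance and separated all 9 libraries with dexamethasone from the 9 without. The second component, with 5.37%, separated 1 library from the rest: replicate 2 of the 20 µM ginsenoside group scored -47.9. In that library 2.79% of counts came from mitochondrially encoded genes, against 1.26% to 1.91% in the other 17 libraries. Ribosomal protein genes took 1.16% of its counts, against 1.34% to 1.71% elsewhere. Relative to the other libraries of its group, ribosomal protein genes were lower in it by a median log2 difference of -0.65 and nuclear genes of oxidative phosphorylation by -0.51, while mitochondrially encoded genes were higher by 1.06. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom from 5.24 to 89.2.

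Dexamethasone raised the classic targets of the glucocorticoid receptor and lowered the growth factor gene Igf1. Serpina3n, a secreted serine protease inhibitor with close paralogs (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329 in GRCm38, protein coding), went from 0.191 ± 0.0607 CPM in controls to 358 ± 29.6 CPM (SD, n = 3), a log2 fold change of 10.87 ± 0.12 (SE; adjusted p = 1.8e-20, edgeR quasi-likelihood test). Fkbp5, a co-chaperone that restrains the receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose from 23.8 ± 0.996 to 428 ± 12.8 CPM. Tsc22d3, an anti-inflammatory receptor target, rose from 58.2 ± 0.41 to 557 ± 25.3 CPM, and Klf15, a transcription factor of muscle amino acid breakdown, from 0.284 ± 0.0416 to 11.1 ± 0.423 CPM. Igf1, the main growth factor for muscle (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042), fell from 110 ± 3.91 to 9.82 ± 3.09 CPM, a log2 change of -3.49 ± 0.20. In all, 6755 of 15436 genes changed at an adjusted p below 0.05, with 3177 higher and 3578 lower, and 534 and 991 of these moved by more than 2-fold. Without a correction for library composition the split was 2368 higher and 4393 lower. The 3 libraries of each group did not overlap for 59.3% of genes, where chance gives 10%. For 10 and 20 µM ginsenoside the share was 12.1% and 11.7% against control and 10.8% and 14.9% against dexamethasone alone. Between the doses it was 11% without dexamethasone and 8.89% with it.

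**Figure D1:**
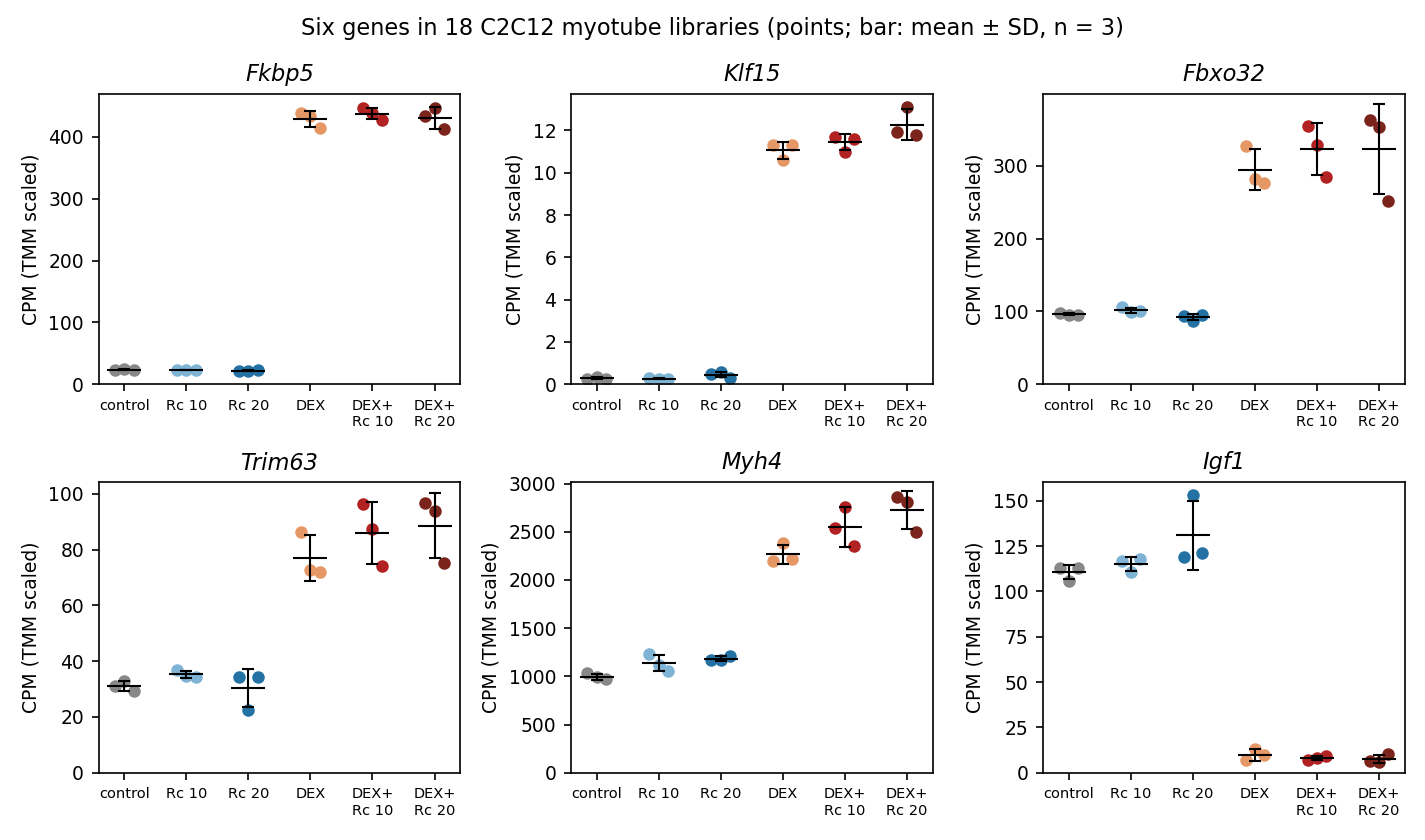
CPM (y axis, TMM scaled) of Fkbp5, Klf15, Fbxo32, Trim63, Myh4 and Igf1 in the 6 groups; Rc stands for ginsenoside Rc with its dose in µM and DEX for dexamethasone, points are libraries and bars are mean ± SD, n = 3. Fkbp5 lies at 23.8 CPM in controls and 428 CPM with dexamethasone, and Igf1 falls from 110 to 9.82 CPM.

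Of 29 measured glucocorticoid receptor targets, 25 rose and 2 fell, with a median log2 change of 1.67 (camera adjusted p = 4.8e-18). Per1, a clock gene with a receptor binding site, rose by 1.92, and Pdk4, which restrains glucose oxidation, by 2.87. Among 21 measured atrophy genes 10 rose and none fell (0 of 21), and the list passed (median 0.16, adjusted p = 0.00064). Fbxo32, the muscle ubiquitin ligase atrogin-1 (chromosome 15, 58175879 to 58214932), went from 96.3 ± 1.35 to 295 ± 28 CPM. Trim63, the ligase MuRF1 (chromosome 4, 134315120 to 134329629), went from 31.1 ± 1.73 to 77 ± 8.11 CPM, and the metal-binding gene Mt1 rose by 3.73. Foxo1, a transcription factor that drives atrophy genes, fell by 0.39, and Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 0.67. Mstn, the growth inhibitor myostatin, lay close to the detection floor of 3 counts at 0.24 ± 0.129 against 0.0975 ± 0.0758 CPM (adjusted p = 0.083). Myog, a myogenic transcription factor, did not differ detectably, with a log2 change of -0.06 (95% interval -0.24 to 0.13).

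Sarcomere, sterol biosynthesis and adipocyte lists were among those higher with dexamethasone. Bulk RNA does not part changes within myotubes from a changed share of undifferentiated cells in the culture. This was not tested for dexamethasone, with which cell cycle and undifferentiated myoblast genes fell. Of 41 sarcomere genes 25 rose and 8 fell (median 0.25, camera adjusted p = 0.00021; adjusted p = 0.24 with an estimated correlation). Myh8, the neonatal myosin heavy chain, went from 521 ± 8.41 to 1410 ± 79.7 CPM, and Myh4, the fast adult myosin, from 996 ± 29 to 2270 ± 97.3 CPM. In the sterol biosynthesis list 25 of 26 genes rose and 1 fell (median 0.79, adjusted p = 4.5e-07; adjusted p = 0.37 with an estimated correlation), including Hmgcs1 (1.07), an enzyme of the mevalonate pathway. Of 8 adipocyte markers 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 1.12, adjusted p = 2.9e-05), with the lipid droplet gene Plin4 up by 5.20 and the transcription factor Cebpa by 2.34. Fatty acid synthesis (10 of 15 up, 2 down; adjusted p = 0.026), nuclear oxidative phosphorylation (19 of 56 up, 0 down; 0.00074) and autophagy and lysosome genes (15 of 30 up, 2 down; 0.0011) also passed, and were lost with an estimated correlation (adjusted p = 0.52, 0.56 and 0.17). Mitochondrial biogenesis and dynamics (16 of 31 up, 0 down) passed at 0.00057 and heat shock genes (7 of 22 up, 1 down) at 0.02, the latter lost with an estimated correlation (adjusted p = 0.33).

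Among the lists that were lower were those of division, matrix, stress response and inflammatory genes. Of 34 cell cycle genes 33 fell and 1 rose, with a median of -2.07 (camera adjusted p = 1.4e-17; adjusted p = 0.11 with an estimated correlation). Aurka, a mitotic kinase, changed by -2.65, Ccnb2, a mitotic cyclin, by -3.07, and the proliferation marker Mki67 by -3.41. In the integrated stress and unfolded protein response list 27 of 34 genes fell and 0 rose, or 29 adjusted over the list alone (median -0.36, adjusted p = 3e-08), including the amino acid transporter gene Slc7a5 (-0.74) and Chac1 (-0.83), which degrades glutathione. Of 32 fibroblast and matrix genes 25 fell and 5 rose (median -0.77, adjusted p = 1e-06; 0.11 with an estimated correlation). Thbs1, a matrix glycoprotein, went from 1660 ± 32.5 to 420 ± 12.1 CPM, while the matrix-associated growth regulator Ccn2 rose by 2.30. Undifferentiated myoblast markers (13 of 18 down, 4 up; adjusted p = 0.00047), osteoblast and chondrocyte markers (7 of 9 down, 0 up; 0.00064) and inflammatory genes (19 of 30 down, 7 up; 0.0065) also passed. Ptgs2, the inducible cyclooxygenase, changed by -2.62, and Lif, a cytokine, by -1.92. TGF-beta and myostatin signalling genes (18 of 35 down, 8 up) passed at 0.025 and were lost with an estimated correlation (adjusted p = 0.17); among them the BMP antagonist Grem1 changed by -2.72.

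The other 13 lists did not pass camera. These were fatty acid oxidation (12 of 29 up, 4 down; adjusted p = 0.054), myogenic regulators (10 of 26 up, 4 down; 0.055), mitochondrially encoded proteins (2 of 13 up, 0 down; 0.086), circadian clock (10 of 20 up, 4 down; 0.096) and p53 targets (12 of 28 up, 8 down; 0.099). IGF, insulin and mTOR signalling (15 of 29 up, 9 down; 0.14), proteasome subunits (4 of 31 up, 0 down; 0.31), antioxidant defence (10 of 32 up, 6 down; 0.34) and ribosomal proteins (0 of 43 changed; 0.45) did not pass either. The same held for replication-dependent histones (2 of 9 up, 1 down; 0.5), the aryl hydrocarbon receptor list (5 of 16 up, 7 down; 0.59), interferon response (5 of 27 up, 7 down; 0.59) and glycolysis and hypoxia (8 of 33 up, 9 down; 0.63). Interferon genes had a median of 0.02 and a mean of -0.20. The medians of the glycolysis, interferon and proteasome lists changed sign without the composition correction. Within these lists Pik3r1, a regulatory subunit of PI3 kinase, rose by 1.18, Igfbp4, which binds IGF, fell by 1.62, and Car9, a hypoxia-induced carbonic anhydrase, fell by 1.52.

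**Figure D2:**
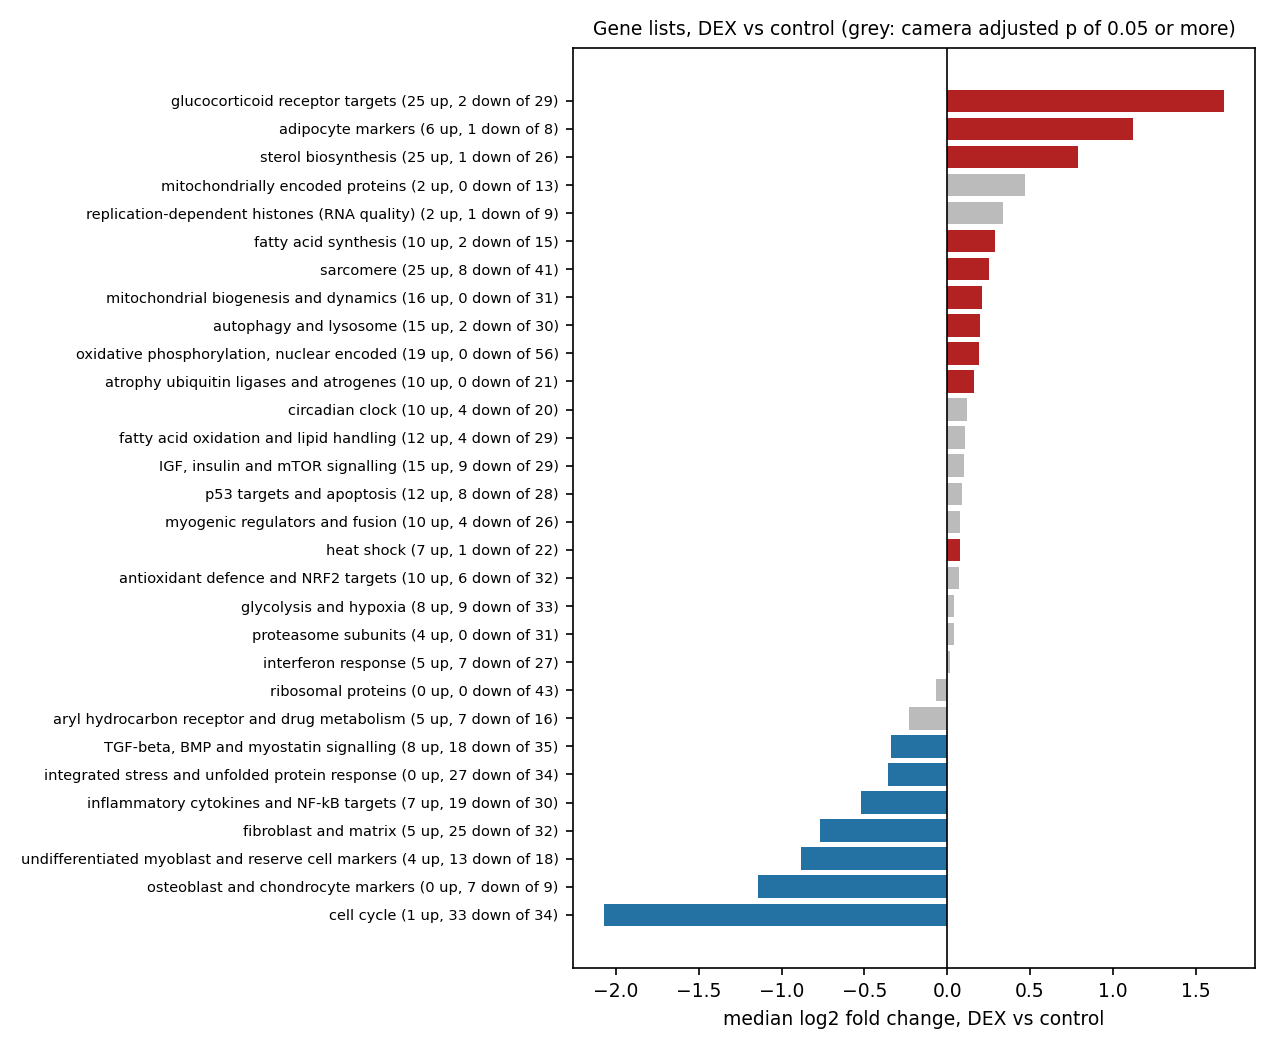
Median log2 fold change (x axis) of each of the 30 gene lists, dexamethasone against control, n = 3 libraries per group; red and blue bars passed camera at an adjusted p below 0.05, grey bars did not, and brackets give the members that rose or fell. The medians run from 1.67 for glucocorticoid receptor targets to -2.07 for cell cycle genes; those of glycolysis, interferon and proteasome genes change sign without the composition correction.

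Ginsenoside Rc at 10 µM without dexamethasone changed 1 gene. Myh8, the neonatal myosin heavy chain (ENSMUSG00000055775, chromosome 11, 67277124 to 67308634 in GRCm38), rose from 521 ± 8.41 to 686 ± 6 CPM (SD, n = 3), a log2 change of 0.40 ± 0.05 (adjusted p = 0.011). The collagen gene Col23a1 was next, at -0.46 ± 0.08 (adjusted p = 0.11). As a list, sarcomere genes passed camera with a median of 0.07 and 36 of 41 above 0 (adjusted p = 2.4e-10), matrix genes with -0.06 and 6 of 32 above 0 (0.00073) and glycolysis genes with 0.05 (0.026). With an estimated correlation the adjusted p were 0.36, 0.68 and 0.68, and only Myh8 of these genes passed, over all genes or adjusted over the list alone. The difference in the mean log2 CPM of matrix genes went from -0.08 to -0.04 without replicate 2 of the treated group, and that of glycolysis genes from 0.05 to 0.02 without it and to 0.08 without replicate 3. DESeq2 called 5 genes and 392 had an unadjusted p below 0.05. Leaving out any 1 of the 6 libraries gave 0 genes, a model of these groups alone 8, and a model without the library of the 20 µM group that stands apart 3.

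At 20 µM without dexamethasone 16 genes changed, 2 higher and 14 lower. Myh8 rose further from control, to 740 ± 30 CPM (log2 change 0.51 ± 0.05, adjusted p = 0.00033), and Fbln7, a secreted matrix adhesion protein, rose by 0.66 ± 0.11 (adjusted p = 0.027). Edn1, the vasoconstrictor endothelin-1 (chromosome 13, 42301476 to 42307990), changed from 3.32 ± 0.291 to 1.62 ± 0.274 CPM (-1.04 ± 0.13, adjusted p = 0.0014). Col23a1, a transmembrane collagen (ENSMUSG00000063564, chromosome 11, 51289920 to 51583918), changed by -0.70 ± 0.08 (0.00041), the laminin chain Lamb3 by -0.55 ± 0.07 (0.002), the ectonucleotidase Nt5e by -0.52, and Axin2, a feedback inhibitor of Wnt signalling, by -0.51. DESeq2 called 101 genes here, and 1434 had an unadjusted p below 0.05. Without replicate 2 of the treated group, the library that stands apart, 44 genes passed; without replicate 3 of it 7 passed, without control replicates 1, 2 and 3 the counts were 5, 7 and 6, and a model of these 2 groups alone gave 0 genes.

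By lists, sarcomere genes were higher at 20 µM (median 0.09, 34 of 41 above 0, camera adjusted p = 2.1e-07), with 1 gene past the threshold over all genes and 6 adjusted over the list alone. Matrix genes were lower (median -0.11, adjusted p = 9e-06; 0 over all genes, 6 lower adjusted over the list alone), as were stress response genes (median -0.08, adjusted p = 1.1e-05; 0 and 6). All 3 were lost with an estimated correlation (adjusted p = 0.39 each) and passed without the library that stands apart (5.3e-12, 1.9e-07 and 0.0002). Ribosomal protein genes (median -0.15, adjusted p = 0.00014) and mitochondrially encoded genes (0.55, 0.014) passed too, and both moved with that library, whose share of mitochondrial counts was 2.79%. Without it their adjusted p were 0.24 and 0.3, and with an estimated correlation 0.66 each. The difference in mean log2 CPM went from -0.17 to 0.02 for ribosomal protein genes without it (-0.27 without replicate 1 or 3 of the group), from 0.20 to 0.04 for mitochondrially encoded genes (0.36 without replicate 3, 0.13 without control replicate 2) and from -0.13 to -0.08 for stress response genes.

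In dexamethasone-treated myotubes, 10 µM ginsenoside Rc changed 4 genes. Lgr6, a receptor for R-spondins that strengthen Wnt signalling, changed by -0.64 ± 0.10 (log2 ± SE, adjusted p = 0.035), Fgfbp1, which carries fibroblast growth factors, by -0.71 ± 0.11 (0.035) and Col23a1 by -0.54 ± 0.09 (0.043). Tm6sf1, a membrane protein gene, rose by 0.32 ± 0.05 (0.043). Without the composition correction 0 genes were higher and 4 lower. DESeq2 called 16 genes, 594 had an unadjusted p below 0.05, and leaving out a library gave 0 genes in 5 cases and 1 gene without replicate 3 of the combined group. A model of these groups alone gave 1 gene, and a model without replicate 2 of 20 µM alone, which stands apart, 15. Sterol genes passed camera (median 0.19, 24 of 26 above 0, adjusted p = 2e-08), as did fatty acid synthesis (0.15, 8.5e-06), glycolysis (0.04, 0.00081), sarcomere (0.02, 0.042), cell cycle (-0.12, 0.0095) and TGF-beta genes (-0.04, 0.022). With an estimated correlation the adjusted p of these lists lay between 0.69 and 0.75, and 0 of their genes passed over all genes; adjusted over the list alone, 2 sarcomere, 1 fatty acid synthesis and 1 glycolysis gene were higher. Without dexamethasone replicate 2 only the sarcomere list passed (adjusted p = 0.0095), and the adjusted p was 0.71 for sterol biosynthesis, 0.15 for fatty acid synthesis, 0.066 for glycolysis and hypoxia, 0.9 for cell cycle and 0.19 for TGF-beta, BMP and myostatin signalling; without replicate 2 of 20 µM alone that of sarcomere was 0.053. The difference in the mean log2 CPM of sterol genes was 0.21, and 0.03 and 0.41 without dexamethasone replicates 2 and 1 and 0.11 without replicate 1 of the combined group. For fatty acid synthesis it was 0.16, and 0.07, 0.25 and 0.09 in these cases. For cell cycle genes it was -0.11, and 0.01, -0.23 and 0 in these cases and -0.20 without replicate 3 of the combined group. For sarcomere and TGF-beta genes it was 0.03 and -0.05, with 0.01 and -0.08 without dexamethasone replicate 1, 0.07 and -0.03 without replicate 1 of the combined group, and 0.01 and -0.08 without its replicate 3.

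At 20 µM, 57 genes differed between the combined treatment and dexamethasone alone, 18 higher and 39 lower. Gja5, the gap junction protein connexin 40 (ENSMUSG00000057123, chromosome 3, 96904693 to 97077416), went from 21.9 ± 2.6 to 10.3 ± 0.775 CPM (-1.09 ± 0.13, adjusted p = 0.00065). Lgr6 (ENSMUSG00000042793, chromosome 1, 134983301 to 135105276) went from 8.74 ± 1.22 to 4.18 ± 0.04 CPM (-1.06 ± 0.10, adjusted p = 8.9e-05), and Col23a1 changed by -0.90 ± 0.09 (0.00012). The matricellular gene Ccn1 changed by -0.54, Tnfaip3, a brake on NF-kB, by -0.30, and the TGF-beta receptor gene Tgfbr2 by -0.25. Fbln7 rose by 0.60, Grb10, an adaptor that restrains insulin signalling, by 0.56, the zinc exporter gene Slc30a1 by 0.41, Myh8 by 0.33 and Actn2, which anchors thin filaments in the Z-disc, by 0.25. DESeq2 called 251 genes and 1351 had an unadjusted p below 0.05. The count rested on single libraries: it was 89, 14 and 24 without dexamethasone replicates 1, 2 and 3, and 9, 6 and 224 without replicates 1, 2 and 3 of the combined group. Without replicate 2 of 20 µM alone, which stands apart and is in the model but not in this comparison, it was 341.

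**Figure D3:**
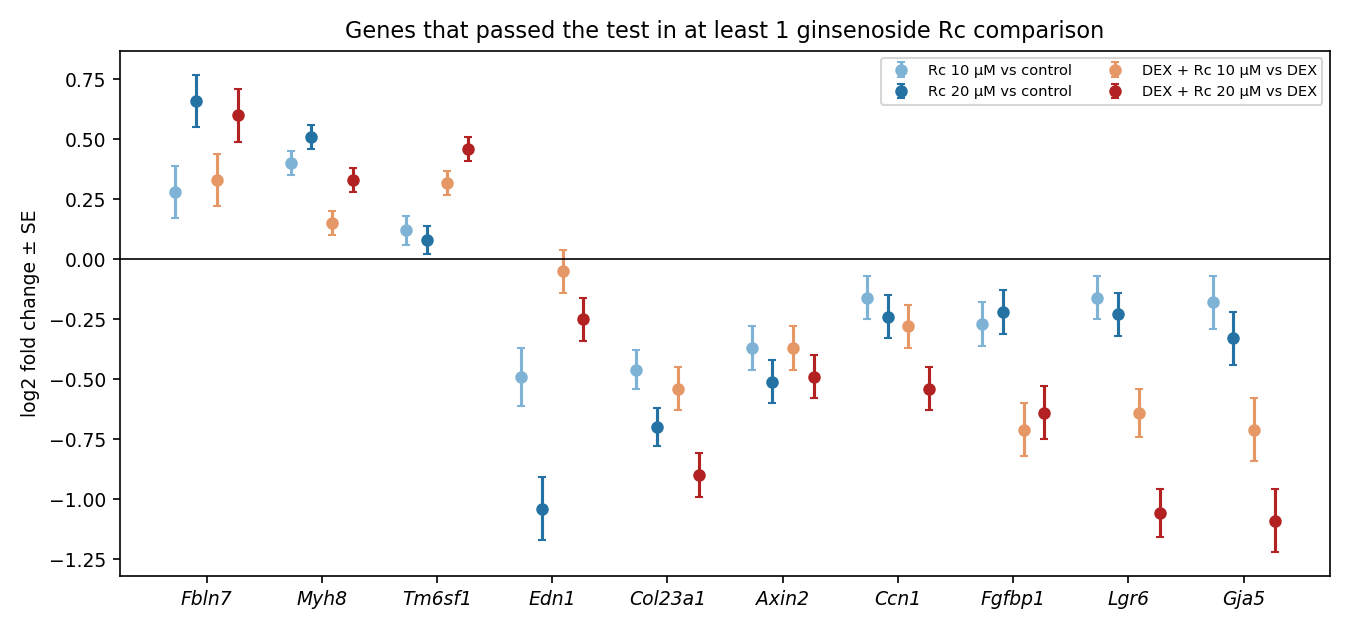
Log2 fold change ± SE (y axis) of 10 genes that passed in at least 1 ginsenoside comparison, at 10 and 20 µM (Rc), against control (blue) and against dexamethasone alone (orange and red), n = 3 libraries per group. Col23a1 is at -0.70 and -0.90 at 20 µM without and with dexamethasone, and Lgr6 at -0.23 and -1.06.

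Sterol genes were the list that differed most between 20 µM ginsenoside with dexamethasone and dexamethasone alone. All 26 lay above 0 with a median of 0.45 (camera adjusted p = 1.9e-21), but 0 passed over all genes and 23 adjusted over the list alone. Fatty acid synthesis genes were similar (median 0.33, adjusted p = 1e-11; 0 over all genes, 12 of 15 adjusted over the list alone). Cell cycle genes were lower (median -0.26, 4.9e-07; 0 and 2 of 34), as were matrix genes (-0.16, 2e-10; 1 and 4 of 32), TGF-beta genes (-0.10, 0.0023), undifferentiated myoblast markers (-0.10, 0.0087), aryl hydrocarbon receptor genes (-0.09, 0.018) and ribosomal proteins (-0.08, 0.01). Glycolysis (0.07, 2.6e-05), autophagy (0.06, 0.0081), oxidative phosphorylation (0.05, 0.023), mitochondrial biogenesis (0.04, 0.021) and sarcomere genes (0.02, 0.028; 3 higher over all genes, 6 higher and 1 lower adjusted over the list alone) passed in the other direction. None of these 13 calls held with an estimated correlation: the adjusted p was 0.14 for sterol, 0.12 for fatty acid synthesis and for matrix, and 0.41 for cell cycle genes. Without dexamethasone replicate 2 the calls of autophagy and lysosome (0.24), oxidative phosphorylation, nuclear encoded (0.41) and aryl hydrocarbon receptor and drug metabolism (0.06) ended. The difference in the mean log2 CPM of sterol genes went from 0.47 to 0.28 without that library, and that of cell cycle genes from -0.24 to -0.13. For cell cycle genes it was -0.16 without replicate 1 or 2 of the combined group and -0.42 without replicate 3. Autophagy genes went from 0.05 to 0.03 and oxidative phosphorylation genes from 0.05 to 0.02 without dexamethasone replicate 2, the latter also to 0.03 without replicate 3 of the combined group. Ribosomal protein genes went from -0.08 to -0.04 and -0.12 without replicates 2 and 3 of that group. Sarcomere genes, at 0.03, went to 0.06 and 0 in these cases, and to 0.01 and 0.05 without dexamethasone replicates 1 and 2. The dexamethasone libraries of 1 group differed widely in the sterol list, with mean log2 CPM of 7.08, 6.33 and 6.69 with dexamethasone alone and 7.22, 7.31 and 6.97 with 20 µM added.

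**Figure D4:**
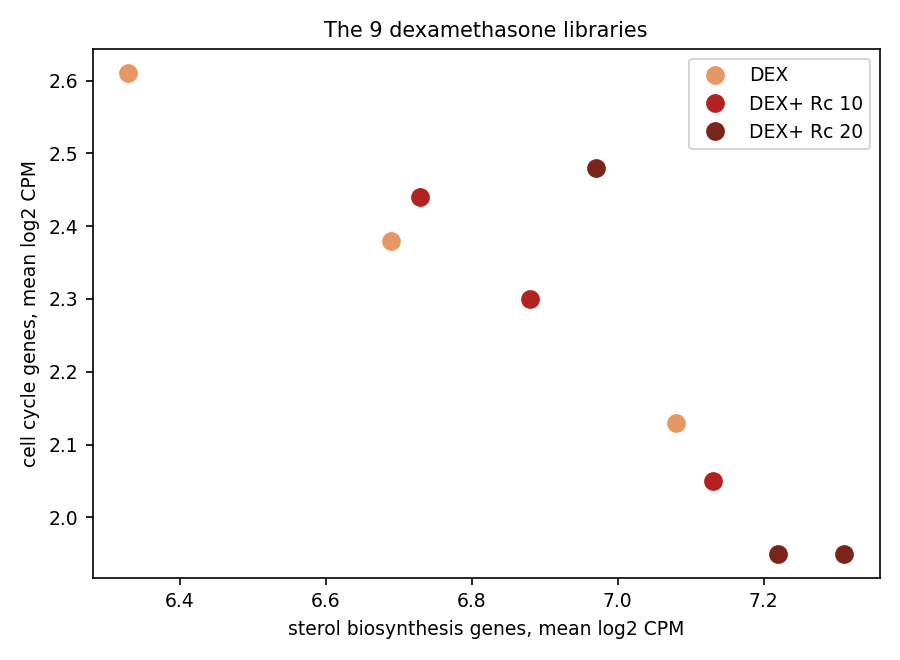
Mean log2 CPM of sterol biosynthesis genes (x axis) against cell cycle genes (y axis) in the 9 libraries with dexamethasone, alone or with 10 or 20 µM ginsenoside Rc; points are libraries, n = 3 per group. The library lowest in sterol genes (6.33) is the highest in cell cycle genes (2.61).

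Ginsenoside Rc did not lower the atrophy ligases that dexamethasone raised by an amount these data could detect. Against dexamethasone alone, 20 µM moved Fbxo32 by 0.13 on the log2 scale (95% interval -0.10 to 0.36, adjusted p = 0.91), at 323 ± 61.7 against 295 ± 28 CPM. Trim63 moved by 0.20 (-0.08 to 0.49, 0.81), Fkbp5 by 0.01 (-0.08 to 0.10) and Klf15 by 0.15 (-0.02 to 0.32). At 10 µM the values were 0.13 for Fbxo32 (-0.10 to 0.36) and 0.16 for Trim63 (-0.13 to 0.44). These intervals take no account of the replicate number, along which both ligases fell in each group with dexamethasone. Of the 57 genes called at 20 µM, 43 moved in the direction in which dexamethasone had moved them and 9 in the opposite direction, and the rest had not changed with dexamethasone. All 4 genes called at 10 µM moved with dexamethasone. Among the 6755 genes changed by dexamethasone, 38.4% lay opposite to it at 10 µM and 29.7% at 20 µM. Both comparisons share the dexamethasone libraries, and unchanged groups simulated against those libraries gave 56.9% and 57.1%. Each gene was simulated independently, so the simulation holds no shift shared by many genes of a library. Deviations of the real libraries from their groups had slopes on the dexamethasone effect of -0.068 to 0.041. The gap from the simulated shares therefore decides nothing about the ginsenoside.

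A dexamethasone score was built from genes that moved by more than 2-fold in libraries outside each comparison. At 10 µM it used 631 higher and 1108 lower genes and stood at -1.27 in controls, 2.01 ± 0.14 with dexamethasone and 2.17 ± 0.14 with both (SD, n = 3). At 20 µM, with 569 and 1029 genes, it stood at -1.25 ± 0.02, 2.19 ± 0.14 and 2.49 ± 0.22. The differences of 0.16 and 0.29 were 4.98% and 8.57% of the dexamethasone effect and lay above it, each with p = 0.2 in a two-sided exact permutation test whose smallest possible p is 0.1. The difference at 10 µM was 0.09 without dexamethasone replicate 2 or without replicate 1 of the combined group, and with no minimum fold for the genes the differences were 0.081 and 0.164. Ginsenoside alone differed from control by 0.08 and 0.11 (exact p = 0.1 each, the smallest possible). By fry, which asks whether the signature genes moved one way on balance, the p was 0.12 at 10 µM and 0.0062 at 20 µM, both upward, and 68.7% and 74.6% of the signature genes moved further from control. Fry pools the spread of all libraries, and the score at 20 µM had an SD of 0.02 in both groups without dexamethasone. With dexamethasone the SD was 0.14 and 0.22, so the fry p may be too small.

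**Figure D5:**
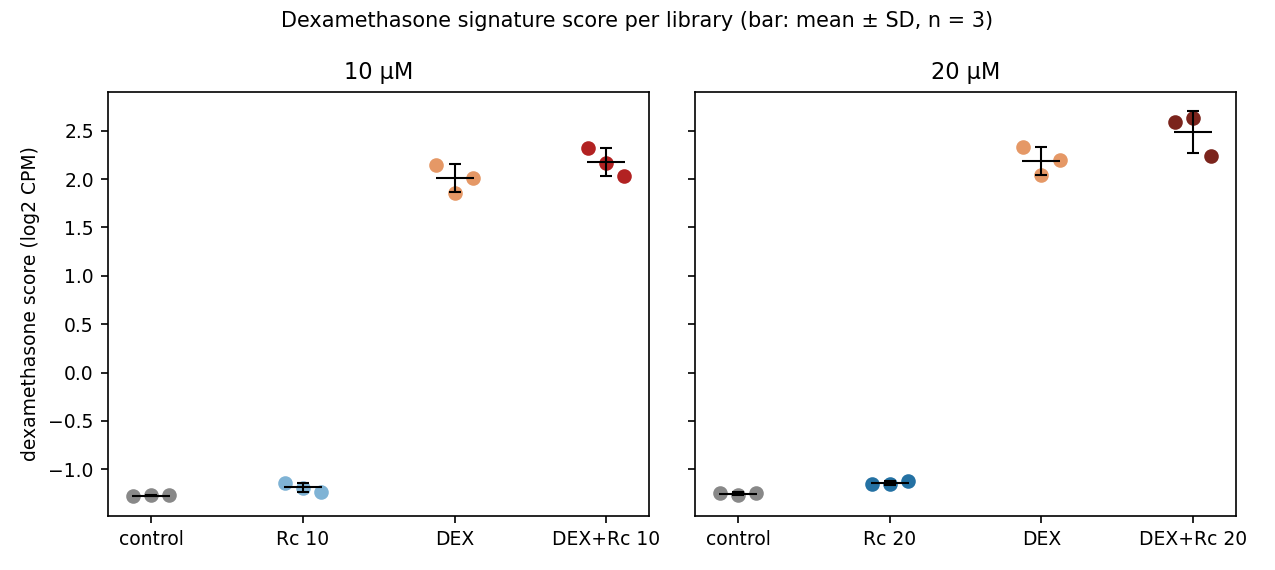
Dexamethasone score of each library (y axis, mean log2 CPM of raised genes minus that of lowered genes) at 10 µM (left) and 20 µM (right); points are libraries, bars are mean ± SD, n = 3. Dexamethasone alone is at 2.01 and 2.19 and dexamethasone with ginsenoside Rc at 2.17 and 2.49, with overlapping libraries.

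Dexamethasone also changed many genes in ginsenoside-treated myotubes. Against 10 µM ginsenoside alone, dexamethasone after 10 µM changed 6820 genes (3264 higher, 3556 lower), and the same comparison at 20 µM changed 7555 genes (3631 higher, 3924 lower). In models of the compared groups alone the counts were 8076 and 5103, against 7934 without ginsenoside, and whether the extent of the response differed was not tested. Without the composition correction the splits were 2449 against 4374 and 2921 against 4519. Across genes, which are not independent replicates, the dexamethasone fold changes without and with ginsenoside correlated at r = 0.896 for 10 µM and 0.915 for 20 µM, from libraries that the comparisons do not share. Of genes called in both, 2759 were higher and 3100 lower in both at 10 µM, where independent lists would share 672 and 824, and 0 went in opposite directions. At 20 µM 2729 and 3124 were shared, against 747 and 910, again with 0 opposite. Glucocorticoid receptor targets rose (24 of 29 at each dose, 3 down), Serpina3n by 10.35 and 10.41, and Igf1 changed by -3.82 and -4.13. Nuclear oxidative phosphorylation genes rose in 23 and 31 of 56 cases (medians 0.20 and 0.29; adjusted p = 0.55 and 0.46 with an estimated correlation). The second count includes the library that stands apart, where these genes were lower by -0.51.

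Whether the ginsenoside effect itself differed with dexamethasone was tested as an interaction, and 0 genes passed at either dose by edgeR. Ginsenoside alone was given for 36 h, while the combined groups had 12 h of it before dexamethasone. Unless it stayed on during dexamethasone, the interaction also compares exposures of different length. At an unadjusted p below 0.05 there were 327 genes at 10 µM and 816 at 20 µM, and DESeq2 called 0 and 1. Lgr6 came nearest at 20 µM, with a difference of -0.84 ± 0.13 (adjusted p = 0.12). Edn1, raised by dexamethasone by 2.61, had an interaction of 0.79 ± 0.16 (0.47), and Fbxo32 one of 0.19 ± 0.15 (0.88). Leaving out the library that stands apart gave 2 genes at 20 µM, Lgr6 (-0.83 ± 0.13, adjusted p = 0.026) and Vgll2, a muscle transcription cofactor (0.76 ± 0.12, 0.026). Across genes the ginsenoside effects without and with dexamethasone correlated at r = 0.006 for 10 µM and 0.18 for 20 µM (Spearman's rho 0.117 and 0.14), and at r = 0.217 for 10 µM over genes with an average log2 CPM of at least 3.

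The 2 doses were also compared directly. No gene passed between 20 and 10 µM, either without dexamethasone (0 by edgeR, 3 by DESeq2, 1385 at an unadjusted p below 0.05) or with it (0 by both tools, 437 unadjusted). Lamb3 lay closest without dexamethasone, at -0.47 ± 0.07 (adjusted p = 0.077), and 1 gene passed without replicate 1 or without replicate 2 of the 20 µM group. With dexamethasone 9 lists passed camera, 4 higher and 5 lower, and 0 with an estimated correlation. Among them, sterol genes were higher at 20 than at 10 µM (median 0.25, camera adjusted p = 1.4e-12; 0.42 with an estimated correlation) and matrix genes lower (-0.12, 1.8e-11; 0.19). The libraries overlapped in mean log2 CPM of sterol genes, with 7.13, 6.88 and 6.73 at 10 µM and 7.22, 7.31 and 6.97 at 20 µM. Without dexamethasone 4 lists passed and 0 with an estimated correlation: glycolysis (-0.09), stress response (-0.08), ribosomal protein (-0.15) and mitochondrially encoded genes (0.48), the last 2 of which moved with the library that stands apart. That library was also the lowest of its group in the mean log2 CPM of the other lists. It had 7.05 for glycolysis genes (7.26 and 7.16 in replicates 1 and 3) and 5.82 for stress response genes (5.96 and 5.98). The effects of the 2 doses share their reference libraries, so part of their likeness is built in. Without dexamethasone they correlated at r = 0.429 across genes, where unchanged groups simulated against the same libraries gave 0.489 (covariance 0.0311 against 0.0295), and 57.6% of genes had the same sign against 66.6%. With dexamethasone r was 0.493 against 0.506 (covariance 0.0363 against 0.0311), and 73.6% of genes had the same sign against 66.8%. Myh8 was higher at both doses without dexamethasone, and with it Tm6sf1 was higher and 3 genes (Lgr6, Col23a1 and Fgfbp1) lower at both, while 20 simulations with unchanged groups shared at most 0 calls. The simulated genes varied independently. Shifts shared by many genes of a library, which can move signs and calls together, are not covered.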

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

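The counts of other splits and of genes passing again without a library or with the sterol level, and the tests of mixed-in RNA and of list slopes, were chosen after the results they bear on were seen.

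The lists below drew attention because a test of the difference itself, the interaction in edgeR and camera, passed for them although 0 single genes did. As for single genes, the length of exposure to the ginsenoside may have differed between the settings compared. At 20 µM the ginsenoside effect on sterol genes was a median log2 change of 0.01 without dexamethasone (-0.01 without the composition correction) and 0.45 with it (camera adjusted p of the difference 5.7e-13). Fatty acid synthesis genes moved by 0.03 and 0.33 (7.7e-06) and glycolysis genes by -0.05 and 0.07 (3.8e-06). Cell cycle genes moved by -0.02 and -0.26 (0.00031), undifferentiated myoblast markers by 0 and -0.10 (0.0052), myogenic regulators by 0.06 and -0.03 (0.0056) and sarcomere genes by 0.09 and 0.02 (0.012). Nuclear oxidative phosphorylation genes moved by -0.07 and 0.05 (0.0056) and stress response genes by -0.08 and -0.04 (0.014). At 10 µM sterol genes moved by 0.01 and 0.19 (6.9e-05), fatty acid synthesis genes by 0 and 0.15 (0.007) and sarcomere genes by 0.07 and 0.02 (0.017). With an estimated correlation the 12 adjusted p rose to between 0.52 and 0.98. Without replicate 2 of the 20 µM group, in which oxidative phosphorylation genes were low, the adjusted p was 0.11 for that list, 0.06 for myogenic regulators and 0.2 for stress response genes at 20 µM, and 0.052 for fatty acid synthesis at 10 µM. Without dexamethasone replicate 2 all 3 calls at 10 µM ended (sterol biosynthesis 0.78, fatty acid synthesis 0.58, sarcomere 0.25), as did those of cell cycle (0.067), oxidative phosphorylation, nuclear encoded (0.14) and sarcomere (0.099) at 20 µM. Of 25 regroupings drawn, 9 gave at least 9 lists at 20 µM (highest 16) and 16 gave at least 3 at 10 µM (highest 10), so chance is not excluded. For genes, all 25 gave at least 0, with a highest of 5 at 20 µM and 0 at 10 µM.

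The first pattern weighed is replicate 2 of the 20 µM group, which stands apart in ribosomal, oxidative phosphorylation and mitochondrially encoded genes. RNA from a dexamethasone-treated library could have been mixed in, but its deviation from the other libraries of its group had a slope of -0.0057 on the dexamethasone effect over 1525 strongly changed genes, within the range of other libraries (-0.068 to 0.041). A bias in transcript length or GC content could lower short transcripts, but removing those trends left 71.4% of the median deviation of ribosomal and oxidative phosphorylation genes (-0.54 before, -0.39 after, 2 SE 19%). The share of mitochondrial counts in that library, 2.79%, is left without a tested explanation, and a difference in the state of that culture stays open and untested.

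The second pattern is the difference between 20 µM with dexamethasone and dexamethasone alone. Dexamethasone replicate 2, the lowest in sterol genes, might have decided it; without it 14 of the 57 genes passed, which argues against this for those 14 and leaves it open for the others. That 57 of 57 genes kept at least 50% of their fold change without it (median 96.9%) decides nothing, since genes called for a small spread within groups can depend little on 1 library. The libraries could also differ along a sterol and cell cycle axis on which libraries of 1 group differ. The sterol level was fitted as a covariate in a model of the dexamethasone libraries alone. With it 24 of the 57 genes passed (49 in all, adjusted over all genes). This argues against the axis for those 24 and leaves it open for the others. The count reflects the smaller model as well as the covariate. The median share of the fold change left was 84.3% (quartiles 70.1% and 109%; median size 0.39 before and 0.32 after, median SE 0.06 and 0.07). This met the mark set beforehand against the axis, a median and lower quartile above 50%. It decides nothing, since genes called for a small spread within groups can have little slope on the sterol level within groups. For the lists, the difference followed the slope on the sterol score within groups with r = 0.857 across 29 lists (Spearman's rho 0.738). The list changes may thus be that axis rather than the ginsenoside, and both stay open. The slope predicted 0.27 for fatty acid synthesis (0.31 found) and 0.05 for autophagy genes (0.05 found). It predicted 0.01 for glycolysis genes (0.08 found) and -0.08 for sarcomere genes (0.03 found), so not every list followed it.

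Other splits of the same libraries were counted for each comparison. With 3 against 3 there are 10 splits, too few for a share below 0.05. The real split was the 1 with the most genes for dexamethasone against control (6755, highest other 0), for 10 µM and 20 µM against control (1 and 16, highest other 0 each), for 10 µM with dexamethasone (4, 0) and for dexamethasone at 10 and 20 µM (6820, 0; 7555, 194). For 20 µM with dexamethasone against dexamethasone alone, 2 splits gave at least the 57 genes of the real split, and the other gave 122. That split set dexamethasone replicates 2 and 3 and replicate 3 of the combined group against the rest, which parts low from high sterol libraries and points to a structure among these samples. Between doses all 10 splits gave at least the 0 genes found, with a highest of 0. For lists, as many passed in 1 of 10 splits for dexamethasone against control (17, highest other 15) and for dexamethasone at 10 µM (18, 16), and in 2 at 20 µM (17, 17). The number was 6 for 10 µM alone (3, highest other 4), 8 for 20 µM alone (5, 7), 4 for 10 µM with dexamethasone (6, 10) and 2 for 20 µM with dexamethasone (13, 13). Between doses it was 8 without dexamethasone (4, 6) and 3 with it (9, 11).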

How the results depend on the processing

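Leaving out replicate 2 of either group, quality weights, length and GC offsets, covariates and list means without 1 library were chosen after seeing the data; the other settings were planned. Counts stayed within 1.5 times under both other scalings in every comparison. The log2 changes of the always-named genes in dexamethasone against control kept their direction in the 13 settings (12 for Mstn) where they were recorded. They were not recorded with quality weights, with length and GC offsets or in the test against a 1.2-fold change. Of single-gene values, 207 were alike and 2 passed anew under other settings, and 168 were alike, 3 passed anew and 9 turned sign with 1 library left out; the 8 and 12 score values of these kinds kept their sign. Depth limits genes near the floor such as Mstn. Counts below are given in the order 10 µM, 20 µM, 10 µM with dexamethasone and 20 µM with dexamethasone where 4 are listed. DESeq2 gave 5, 101, 16 and 251 genes, 1 in the 20 µM interaction and 3 between doses. Voom with quality weights gave 6, 147, 56 and 957, with 1 between doses and 2 with dexamethasone. Without 20 µM replicate 2 the counts were 3, 44, 15 and 341, with 2 in the 20 µM interaction and 1 between doses, 8 lists between doses, and a correlation of 0.256 between the 20 µM effects; all 57 main genes were kept. With only the compared groups the counts were 8, 0 and 1 for the first 3, from a spread estimated on fewer libraries. Without the low-count filter 2, 28 and 95 genes passed for 10 µM, 20 µM and 20 µM with dexamethasone, and 1 each in the 20 µM interaction and between doses. Against a 1.2-fold change the counts were 0, 2, 0 and 4, and 3440, 3517 and 3940 for dexamethasone at 0, 10 and 20 µM, as the test asks for a larger effect. Over genes with log2 CPM of at least 3 the 10 µM correlation was 0.217. For the rest the cause was not tested.

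Leaving out 1 library of the groups compared gave ranges of 5834 to 6163 genes for dexamethasone, 5915 to 6263 with 10 µM and 6536 to 7964 with 20 µM. The ranges were 0 to 0, 5 to 44, 0 to 1 and 6 to 224 for the ginsenoside comparisons, 0 to 0 and 0 to 2 for the interactions, 0 to 1 between doses and 0 to 0 between doses with dexamethasone. Score differences ranged from 0.09 to 0.235 and from 0.22 to 0.419. Changes near 0 turned sign: Mstn ranged from -0.50 to 0.37 and from -0.28 to 0.44 at 10 and 20 µM with dexamethasone, Foxo1 from -0.05 to 0.02 at 10 µM, and Fkbp5 from -0.02 to 0.04 and Ppargc1a from -0.02 to 0.16 at 20 µM. An estimated correlation left 8, 6 and 6 lists for dexamethasone at 0, 10 and 20 µM and 0 for each other comparison. Fry gave 6 lists for 20 µM with dexamethasone, 25, 26 and 26 for dexamethasone at 0, 10 and 20 µM, and 0 for 10 µM with dexamethasone, both doses alone, the interactions and the dose comparisons. Fry and camera pool the spread of all libraries, so their p may be too small where dexamethasone libraries vary more. Sterol genes had an SD of 0.38 with dexamethasone alone and 0.03 in controls. Without dexamethasone replicate 2, 1 list passed for 10 µM with dexamethasone and 0 for its interaction.

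With the replicate number as a replicate block, 1 gene passed for 10 µM with dexamethasone, and no other count moved by over 1.5 times. Taken over all genes, the numbers showed no general pairing. Over 45 same-numbered pairs the median correlation of deviations was 0.00067 (-0.2 to 0.15), 4 pairs were over 0.1, and 5 of 18 libraries correlated best with their own number. A correlation over all genes does not exclude pairing in single genes. Fbxo32 fell from replicate 1 to 3 with dexamethasone alone (327, 282 and 276 CPM), with 10 µM added (355, 329 and 285) and with 20 µM added (363, 354 and 252). Trim63 fell in the same order (86.4, 72.7 and 72, then 96.4, 87.5 and 74, then 96.9, 93.8 and 75.2 CPM). Myog was lowest in replicate 2 and highest in replicate 3 in each of these groups. Igf1 kept no such order (6.82, 13 and 9.64, then 7.1, 8.27 and 9.23, then 6.32, 5.99 and 10.1 CPM). The main intervals take no account of the replicate number. Neither Fbxo32 nor Trim63 passed against dexamethasone alone in the 13 settings recorded, the replicate block among them.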

Other observations

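The test of undifferentiated cells was chosen after the result it bears on was seen, and so were the relations between lists across libraries; for the Wnt list, the comparison with other splits was added after its first p was seen.

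Among the 9 libraries with dexamethasone, the level of sterol genes was related to that of other lists, none of which shares a gene with it. All p are from two-sided exact permutation tests over 29 relations. Fatty acid synthesis genes were higher where sterol genes were (r = 0.98, exact p = 5.5e-06, adjusted p = 8e-05; rho = 0.98, exact p = 5e-05), with r = 0.96 without the 2 libraries farthest from the median. Autophagy and lysosome genes were too (r = 0.97, exact p = 6.3e-05, adjusted 0.00061; rho = 0.95, exact p = 0.00035; 0.91 without the 2). Matrix genes were lower where sterol genes were higher (r = -0.91, exact p = 0.00033, adjusted 0.0024; rho = -0.93, exact p = 0.00075; -0.92 without the 2), as were cell cycle genes (r = -0.90, exact p = 0.00067, adjusted 0.0032; rho = -0.87, exact p = 0.0045; -0.83 without the 2). Over deviations from group means these relations had r of 0.96, 0.95, -0.92 and -0.90. Aryl hydrocarbon receptor genes were also lower (r = -0.98, exact p = 5.5e-06, adjusted 8e-05; rho = -0.98, exact p = 5e-05; -0.96 without the 2), as were TGF-beta genes (r = -0.90, exact p = 0.00047, adjusted 0.0027; rho = -0.93, exact p = 0.00075; -0.87 without the 2). The same held for undifferentiated myoblast markers (r = -0.87, exact p = 0.0018, adjusted 0.0076; rho = -0.98, exact p = 5e-05; -0.90 without the 2) and myogenic regulators (r = -0.80, exact p = 0.0091, adjusted 0.033; rho = -0.78, exact p = 0.017, adjusted 0.055; -0.72 without the 2), and the other relations did not pass. Glucocorticoid receptor targets gave r = -0.09 (exact p = 0.82, adjusted 0.85; rho = 0, exact p = 1; -0.56 without the 2).

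The third pattern weighed is the higher sarcomere and lower matrix genes with 20 µM alone. Fewer undifferentiated cells in the culture could give both, which would lower cell cycle and undifferentiated myoblast markers too. Their joint median was -0.01, with -0.02 for cell cycle genes (quartiles -0.13 and 0.04) and 0 for myoblast markers, against -0.11 for matrix and 0.09 for sarcomere genes. The members go both ways around a small shift, so this explanation and an effect of the ginsenoside on these genes cannot be told apart here.

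With dexamethasone, 20 µM ginsenoside lowered Axin2, Lgr6 and the ligand gene Wnt10a (log2 changes -0.49, -1.06 and -0.33), which belong to Wnt signalling and may reflect a general fall of Wnt target genes. As a test, 30 other targets were listed with the noticed genes left out, of which 23 were measured. With dexamethasone, 20 µM lowered this list (camera p = 0.00024, 0.017 with an estimated correlation, fry p = 0.0052), with a median of -0.18 and 15 of 23 below 0. The real grouping had the smallest camera p of the 10 splits of these libraries (next 0.0044), 2 other splits also fell below 0.05, and the list score differed by -0.13 (two-sided exact p = 0.1, the smallest possible). Single genes did not pass (0 of 23 by edgeR), and without dexamethasone the camera p was 0.43 at 20 µM and 0.14 at 10 µM, while 10 µM with dexamethasone gave 0.043 (0.15 with an estimated correlation, fry p = 0.21). The list was tested in the libraries in which the first genes were noticed, and a shift shared by many genes of a library is not excluded. Neither leaving out dexamethasone replicate 2 nor the sterol level was tried for it. Without dexamethasone 20 µM changed Axin2 by -0.51, Lgr6 by -0.23 and Wnt10a by -0.26, so the fall of Axin2 was not particular to the combined treatment. A lower Wnt output under the combined treatment is thus a hypothesis from these data, and the difference between the settings with and without dexamethasone was not tested for this list.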
